A study of Schmidtea mediterranea with 10 samples.

How the data were processed

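The asexual planarian flatworm Schmidtea mediterranea (clone W4) was kept at 20 degrees Celsius, per the labels' protocols. Animals were amputated 7 days after feeding, and fragments were collected 30 min, 1 h, 3 h, 6 h or 12 h later. A parallel course used animals amputated 5 days after 6000 rad from a cesium source, a dose used in planarian work to remove the dividing stem cells (neoblasts). Total RNA was extracted with TRIZOL and labelled directly. Each 2-colour array carried RNA of the wounded fragments in Cy5 and RNA of freshly amputated fragments of the same treatment in Cy3, here called the 0 h control. No dyes were swapped, so a dye effect that is the same on every array stays in each ratio to 0 h and cancels between time points and between treatments.

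Each of the 10 GEO samples had 3 arrays. The series' design text gives 3 replicates per condition and 10 animals per replicate, and the 3 arrays of a sample were taken as these replicates, although each sample is described as the first of 3. The labels do not say whether the 3 control extracts of a condition, or the controls of different time points, were separate extracts. The labels pair no arrays, and the blocks used for this were the slide and the run described below. The p-values therefore measure the spread between arrays. If the 3 arrays of a condition shared a control extract, a ratio tested against 0 leaves out the spread between control extracts. If the extracts were separate, that spread is part of the spread between arrays.

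Per the file headers, the arrays were Agilent designs with 60-base probes, read with Feature Extraction 10.1.1.1. The deposited scanner files hold, per the file headers, the mean intensity of each spot and the median intensity of its surroundings in both dyes, without normalization. They also hold processed signals, which are background-subtracted and dye-normalized intensity values, and their log10 ratio of Cy5 over Cy3, all computed by Feature Extraction per the file headers. Flags for outlier spots and for spots well above background, also deposited per the file headers, are coded as 0 or 1. A deposited table of values holds a single column for each sample. The submitters' processing notes name limma without a version, and other steps are not given in the sources used here. Set against the scanner values, each column of the authors' table matched the mean over 3 arrays of loess-normalized log2 ratios of Cy5 over Cy3 without background subtraction, with Pearson r over probes from 0.972 to 0.994 and slopes from 0.948 to 0.988. This settles its log2 scale and its direction. Its column medians lay between -0.003 and 0.023, and whether a further centring was applied is unknown.

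The main values were computed from the mean and background intensities with limma 3.58.1 in R 4.3.3 (with the data.table package 1.17.8 and statmod 1.5.0). Background was corrected with normexp and an offset of 50 over all 45220 spots, the 1417 control spots had weight 0 in loess within each array and were then left out, and the 214 spots with an outlier flag over all 30 arrays were left out. No spot was saturated. Of the 43803 probes, 31459 were well above background on all 3 arrays of at least 1 group in at least 1 dye and were tested. The other 12344 were left out as dim. Where a probe was not well above background on any of the 3 arrays of a group in 1 dye, only a bound is given, as at least N-fold. This bound is the bright dye's mean log2 signal against the higher of the dim probe's own signal and the lowest signal among probes well above background on that array, after loess and Aquantile scaling, and it is open to dye bias.

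All 30 arrays entered 1 linear model with 10 group means, fitted with lmFit and eBayes. Each group mean was tested against 0. Irradiated minus unirradiated ratios were tested at each time, and moderated F tests covered all times. P-values were adjusted by Benjamini-Hochberg within each contrast. A probe was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1, and F tests were called at an adjusted p under 0.05 alone. For the 0 h comparison, the Cy3 channels of 15 irradiated and 15 unirradiated arrays were scaled with Aquantile and compared with slide as a random block, whose consensus correlation was 0.419. Unless stated otherwise, the ± after a mean log2 value is the SD over 3 arrays.

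The probes carry identifiers of 2 kinds (41755 beginning with SMED and 2048 beginning with SmWIOct06). The files do not pair them with gene names, since all 43803 descriptions read Unknown. The rule fixed for this case names, per comparison, at most 2 called probes that rose and 2 that fell, those of largest log2 fold change with the same sign on all 3 arrays. For the F test between times of each course, the 2 probes of lowest adjusted p are named. Any other probe is said to have been chosen after its values were seen. The 24 lists of genes fixed in advance, among them neoblast, wound-response and immediate-early genes, could not be matched to probes, so no list was tested.

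Array layout was examined as a batch. The 30 arrays lay on 8 slides, in 6 runs of 5 consecutive array positions, each run holding 1 array per time point of 1 treatment and each slide holding arrays of up to 2 runs. Deviations of arrays from their group means correlated within runs, with a median r of 0.445 over 60 pairs. Arrays of the same slide but of different runs and groups gave a median r of -0.103 over 13 pairs. Arrays of the same treatment but of other runs, slides and groups gave a lower median r, -0.256 over 110 pairs. Spread shared by a slide is therefore not excluded. The consensus correlation of the log2 ratios was 0.220 for slide and 0.297 for run. Correlations between Cy3 channels had a median of 0.997 within a run, 0.986 between runs of the same treatment and 0.962 between treatments. Treatment and run cannot be crossed, because runs 1 to 3 held unirradiated and runs 4 to 6 irradiated fragments. Only slide 4 held both treatments, with 3 unirradiated arrays and 1 irradiated array. With slide as a fixed effect, the difference between treatments therefore rests on that 1 irradiated array.

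Precision was limited by the number of arrays. The median spot signal per array ranged from 217.9 to 850.2 in Cy3 and from 550.8 to 1439 in Cy5, and 51.4% to 70.8% of the probes were well above background in Cy3 and 53.4% to 91.5% in Cy5. The first run, which is replicate 1 of unirradiated fragments at every time, had the dimmest Cy3 channels. Their medians were 217.9 to 254.9, against 539.0 to 850.2 in the other runs. The calling was tested on simulated arrays with the observed spread and, except for the 0 h comparison, the observed run correlation. In these, 200 of 31459 probes were changed. The spread was drawn separately for each probe, so effects shared by many probes of an array were absent. The false calls below therefore do not give a rate for the real arrays. At 1 h, the test against 0 recovered 88% of simulated 2.38-fold changes and 98% of 4-fold changes in unirradiated fragments, with 1 false call. In irradiated fragments it recovered 90% and 98%, with 6 false calls. The test between treatments at 1 h recovered 74% of 2.38-fold and 98% of 4-fold differences, with 7 false calls. The comparison at 0 h recovered 98% of 2.38-fold differences, with 0 false calls. Its arrays were simulated with the observed slide correlation and no run effect, so false calls from spread between runs were not examined. The F test between times in irradiated fragments recovered 90% of 2.38-fold changes at 1 time, with 1 false call.

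Before the data were examined, these alternatives were fixed. They were Feature Extraction's processed signals, no background subtraction, centring on the array median in place of loess, Aquantile between arrays, no filter and a stricter filter (19732 probes well above background in both dyes on every array), slide as a random or fixed block, fits of the compared arrays alone, array weights (estimated gene by gene, since the REML estimate did not converge), other thresholds, the authors' values, and leaving out each array. Added after seeing the data were run as a block, means per run, a correction for probe base composition, and leaving out the first run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.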

Results

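Wound responses were measured in amputated planarian fragments at 5 times after amputation, in unirradiated animals and in animals irradiated 5 days earlier. The series comprised 30 arrays in 10 groups of 3, 1 group for each treatment and time. Every array gave the log2 ratio of wounded fragments to freshly amputated fragments of the same treatment. The series title sets unirradiated against irradiated wounded animals, so the question addressed is which part of the wound response differs in animals that received 6000 rad. Because no gene names are paired with the probes, changes are described by probe identifier, with the 60-base probe sequence for the main examples.

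Both probes with the highest ratios in unirradiated fragments at 30 min were back near their control by 12 h. Probe SMED_07766_V2_1 (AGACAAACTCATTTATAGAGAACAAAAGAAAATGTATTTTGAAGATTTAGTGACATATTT) stood at a log2 ratio of 3.13 ± 0.11 (SD, n = 3) at 30 min, 3.45 ± 0.19 at 1 h, 2.61 ± 0.33 at 3 h, 1.16 ± 0.66 at 6 h and 0.15 ± 0.27 at 12 h. Probe SMED_23310_V2_1 (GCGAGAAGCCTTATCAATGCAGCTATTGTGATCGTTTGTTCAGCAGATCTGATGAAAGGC) followed the same course, from 2.99 ± 0.13 at 30 min and 3.49 ± 0.18 at 1 h to -0.01 ± 0.37 at 12 h. Limma's adjusted p at 1 h was 7.2e-08 for the first and 9.7e-10 for the second. Probe SMED_30483_V2_1 (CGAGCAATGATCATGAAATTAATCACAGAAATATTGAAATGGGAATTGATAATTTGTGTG) had its highest ratio at 3 h, 2.62 ± 0.36, after 1.24 ± 0.50 at 30 min. SMED_20251_V2_1 (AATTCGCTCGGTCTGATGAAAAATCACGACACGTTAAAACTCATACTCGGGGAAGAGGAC) rose to 2.50 ± 0.26 at 3 h and 2.30 ± 0.16 at 6 h.

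Late risers in unirradiated fragments were SMED_19200_V2_1 (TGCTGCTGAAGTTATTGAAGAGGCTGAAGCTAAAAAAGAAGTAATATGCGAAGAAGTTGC) and SMED_04485_V2_1 (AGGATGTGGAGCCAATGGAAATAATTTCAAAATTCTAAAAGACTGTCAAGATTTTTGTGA). The first stood at 0.13 ± 0.76 at 30 min, 1.60 ± 0.56 at 6 h and 2.30 ± 0.60 at 12 h, and the second at 0.18 ± 0.32, 1.66 ± 0.21 and 1.96 ± 0.33. Among the probes called lower, SMED_31081_V2_1 (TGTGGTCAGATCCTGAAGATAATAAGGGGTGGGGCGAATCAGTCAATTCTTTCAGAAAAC) had the lowest ratio at every time up to 6 h, -2.63 ± 0.41 at 30 min and -3.15 ± 0.55 at 1 h, though its Cy5 signal was well above background on 2 of 3 arrays at these times. SmWIOct06_009236 stood at -1.85 ± 0.82 at 1 h and -2.05 ± 0.71 at 3 h. SMED_22344_V2_1, which was not well above background in Cy5, was at least 3.12-fold lower than its control at 30 min (limma's adjusted p = 0.0015). At 12 h the lowest were SMED_01539_V2_1 at -1.72 ± 0.89 and SMED_15214_V2_1 at -1.69 ± 0.84, which share a run of 55 bases and count as 1 signal. The F test between times called none of these lower probes in either course (limma's adjusted p of at least 0.379). With run as a fixed effect its adjusted p was at least 0.114. A dye effect that is the same on every array is therefore not separated from their low ratios.

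**Figure D1:**
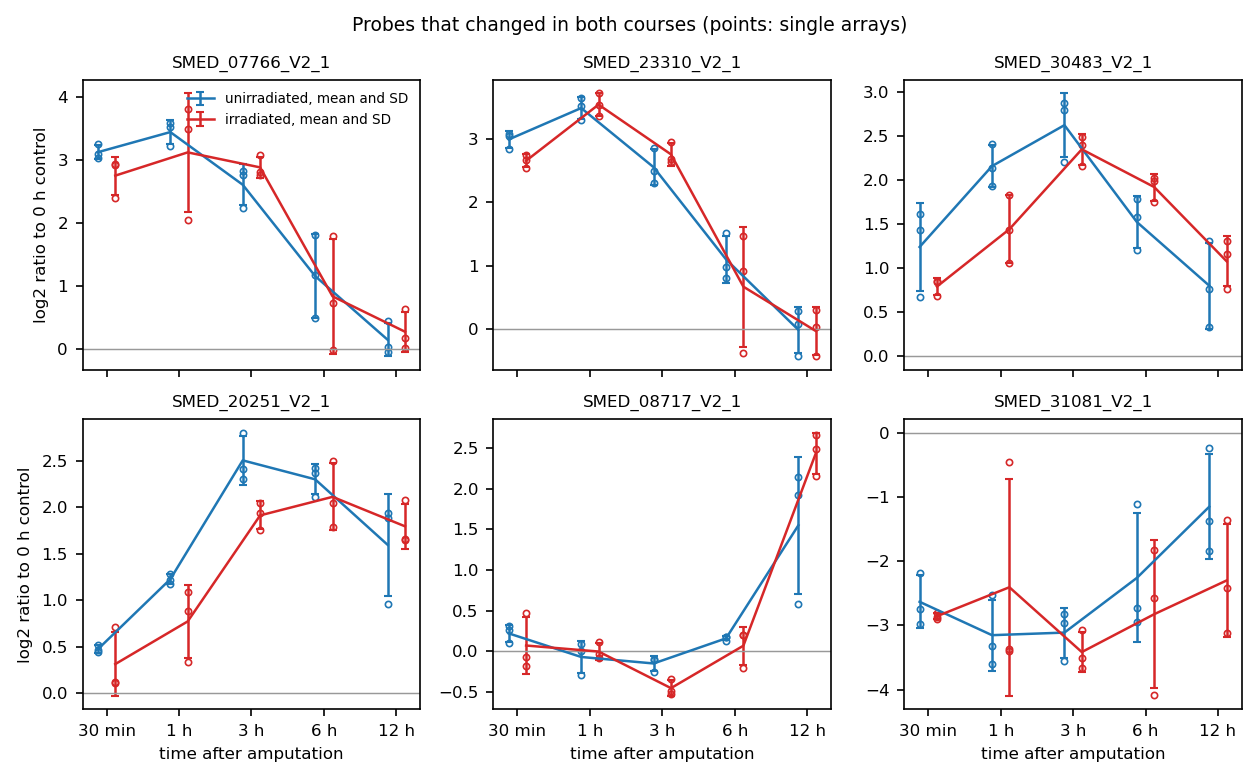
Log2 ratio of wounded fragments to the 0 h control (vertical axis) against time after amputation in equal steps (horizontal axis) for 6 named probes, with unirradiated fragments in blue and irradiated fragments in red; open circles are single arrays, lines join the means and bars are the SD of 3 arrays. SMED_07766_V2_1 and SMED_23310_V2_1 peak at 1 h in both courses (3.45 and 3.12, 3.49 and 3.54) and return close to 0 by 12 h (0.15 and 0.28, -0.01 and -0.03), while SMED_08717_V2_1 rises only at 12 h among these times (1.55 and 2.44). SMED_31081_V2_1 has mean ratios below 0 at every time, and the F test between times called it in neither course.

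Across the 31459 probes tested in unirradiated fragments, 74 were called higher and 40 lower at 30 min, 111 and 40 at 1 h, 184 and 47 at 3 h, 85 and 11 at 6 h, and 69 and 12 at 12 h. In total 348 probes were called at 1 time or more, and 149 of these had their largest absolute change at 3 h, against 63 at 30 min, 62 at 1 h, 31 at 6 h and 43 at 12 h. Only 44 of the 348 were also called by the F test between times, or 115 with run as a fixed effect, so for most the time of the largest change is not settled. At every time 22 probes were called. The bright probes SMED_06409_V2_1 (log2 ratio 2.36 ± 0.20 at 6 h) and SMED_20010_V2_1 (2.26 ± 0.50 at 6 h) are of this kind, as is SMED_00493_V2_2 on the lower side (-1.73 ± 0.45 at 6 h). The F test between times called none of them. From 30 min to 12 h their mean ratios went from 2.66 to 1.92, from 2.40 to 1.94 and from -1.89 to -1.30. Their size depended on the processing. At 6 h SMED_06409_V2_1 stood at 1.62 and SMED_20010_V2_1 at 1.33 in the authors' values, and SMED_06409_V2_1 at 3.97 with centring on the array median. A dye effect that is the same on every array is not separated from such constant ratios.

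The counts depended on single arrays and on scaling. Without replicate 1, 211 probes were called at 30 min, of which 87 were higher and 124 lower, so that the more frequent direction turned, with 336 at 1 h and 804 at 3 h; without replicate 2, 73 at 30 min, 151 at 6 h and 133 at 12 h; and without replicate 3, 69 at 30 min, 72 at 1 h, 102 at 3 h and 62 at 6 h. The split into higher and lower calls moved with scaling. Without background subtraction it was 49 to 15 at 30 min and 111 to 97 at 12 h, with Feature Extraction's processed signals 1080 to 522 at 6 h and 724 to 971 at 12 h, and with base composition corrected 44 to 8 at 30 min. Centring on the array median moved the median of all probes up to between 0.077 and 0.481 and gave 420 to 20, 583 to 61, 735 to 55, 7119 to 10 and 57 to 1 from 30 min to 12 h.

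**Figure D2:**
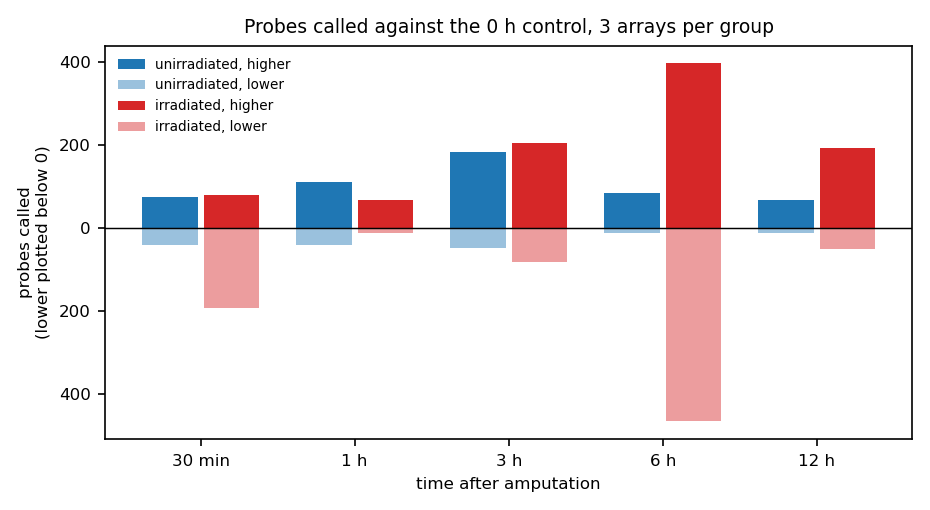
Number of probes called against the 0 h control (vertical axis, higher above 0 and lower below 0) at each time after amputation (horizontal axis), in unirradiated (blue) and irradiated (red) fragments, from 3 arrays per group. The tallest bars, 397 higher and 465 lower in irradiated fragments at 6 h, fall to 133 and 51 without replicate 2 of that group.

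At 30 min and 1 h, both leading higher probes, and the leading lower probe, were shared by irradiated and unirradiated fragments, while the second lower probe differed. SMED_07766_V2_1 stood at 2.76 ± 0.30 at 30 min, 3.12 ± 0.94 at 1 h, 2.89 ± 0.17 at 3 h and 0.28 ± 0.31 at 12 h. SMED_23310_V2_1 stood at 2.66 ± 0.10 at 30 min, 3.54 ± 0.18 at 1 h, 2.76 ± 0.18 at 3 h and -0.03 ± 0.37 at 12 h. SMED_31081_V2_1 was first on the lower side at each of the 5 times, at -2.86 ± 0.05 at 30 min, -3.42 ± 0.31 at 3 h and -2.30 ± 0.88 at 12 h. The F test between times did not call it (limma's adjusted p = 0.791), so a constant dye effect is not separated from its ratio. SMED_00493_V2_2 was second on the lower side at 1 h (-1.71 ± 0.47) and 3 h (-2.37 ± 0.06). At 12 h the highest ratio was that of SMED_08717_V2_1 (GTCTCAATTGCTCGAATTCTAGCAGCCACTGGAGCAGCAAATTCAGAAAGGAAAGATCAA), 2.44 ± 0.26 against 0.07 ± 0.24 at 6 h (limma's adjusted p at 12 h = 4.7e-09), followed by the constant probe SMED_20010_V2_1 at 2.24 ± 0.20 (1.41 in the authors' values). SMED_04036_V2_2 was also called lower at 12 h, but its Cy5 signal was well above background on only 1 of 3 arrays, so no size is given. SMED_12382_V2_1 was barely called lower at 30 min (-2.71 ± 1.06, limma's adjusted p = 0.042) and 6 h (-2.41 ± 0.37, adjusted p = 0.046). It lost both calls with Feature Extraction's processed signals, with centring, with base composition corrected and without any 1 replicate, and it spread widely in other groups, with an SD of 2.49 at 30 min in unirradiated fragments.

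In irradiated fragments 81 probes were called higher and 193 lower at 30 min, 68 and 11 at 1 h, 206 and 82 at 3 h, 397 and 465 at 6 h, and 192 and 50 at 12 h, 1253 in total over the course. Of these, 724 had their largest absolute change at 6 h, against 192 at 30 min, 22 at 1 h, 172 at 3 h and 143 at 12 h. The F test between times also called 88 of the 1253, or 209 with run as a fixed effect, so this tally is not settled for most of them either. The 6 h values rested on replicate 2, whose log2 ratios had an SD over probes of 0.742, against 0.423 and 0.402 in replicates 1 and 3. Without replicate 2, 184 probes were called at 6 h, without replicate 1 1591 and without replicate 3 2036. Both probes with the highest 6 h ratios spread widely over the 3 arrays. For SMED_01378_V2_1r no size is given, since its control was not well above background. With replicate 2 left out it was no longer called (limma's adjusted p = 0.156), as with array weights (adjusted p = 0.271). It stayed called without replicate 1 (adjusted p = 2.6e-04) and without replicate 3 (adjusted p = 0.018). SMED_27563_V2_1 stood at 2.39 ± 3.98 because of replicate 1 alone, at 6.99 against 0.10 and 0.10, and was 0.12 without background subtraction, so it is not counted as a wound response here.

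With single arrays left out, counts at the other times in irradiated fragments were 135 at 30 min without replicate 2, 154, 52 and 48 at 1 h without replicates 1, 2 and 3, and 399 at 12 h without replicate 1. The split into higher and lower calls was 611 to 869, 1182 to 797, 1297 to 866, 2710 to 1827 and 1146 to 659 from 30 min to 12 h with Feature Extraction's processed signals. At 30 min it was 61 to 58 without background subtraction and 62 to 72 with base composition corrected. Centring on the array median gave 170 to 69 at 30 min, 501 to 99 at 3 h, 4251 to 65 at 6 h and 3507 to 33 at 12 h.

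Differences between time points, from which a constant dye effect drops out, separated transient from late probes in both courses. The lowest limma adjusted p of the F test was 1.7e-06 in unirradiated fragments, shared by SMED_23310_V2_1 and SMED_32966_V2_1, and 1.2e-06 in irradiated fragments, for SMED_23310_V2_1. SMED_32966_V2_1 (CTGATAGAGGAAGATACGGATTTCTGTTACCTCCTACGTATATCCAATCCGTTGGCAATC) rose from -0.21 ± 0.02 at 30 min to 0.61 ± 0.04 at 6 h and 1.15 ± 0.17 at 12 h in unirradiated fragments. In irradiated fragments it went from 0.00 ± 0.12 at 30 min to 0.68 ± 0.20 at 6 h and was 2.39-fold above its control at 12 h. The moderated F test called 124 probes in unirradiated and 224 in irradiated fragments. With run as a fixed effect, a choice made after seeing the data, 540 and 957 were called, among them all 124 and all 224. The counts were 5 and 97 with centring on the array median, 239 and 642 without background subtraction, 259 and 544 with slide as a random block, and 8133 and 3341 with array weights. The unirradiated count was 193 with Feature Extraction's processed signals, 52 with the arrays of the course alone and 59 without the first run. Without replicate 1 at 1 h the unirradiated count was 256. The irradiated count was 341 without replicate 1 at 6 h, 2673 without replicate 3 at 6 h and 136 without replicate 2 at 12 h.

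Against the 30 min ratio, and with run as a fixed effect, limma called no probe at 1 h in either course, where 2503 unirradiated and 4615 irradiated probes had an unadjusted p under 0.05; without the run effect the count was also 0 in both. At 3 h, 11 rose and 1 fell in unirradiated and 19 rose and 1 fell in irradiated fragments. At 6 h the counts were 12 and 8 against 103 and 113, and at 12 h 35 and 16 against 106 and 13. Of the probes called at 12 h, 24 were called higher in both courses and 9 lower in both, where independent lists of these sizes would share 0.118 and 0.00661. Base composition may add to this overlap, which was not tested. The 12 h minus 30 min ratio correlated with the C count at r of 0.29 and 0.23 in the courses. For T, r was -0.30 and -0.14, while G and A had opposite signs in the courses.

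The difference between irradiated and unirradiated responses was called for few probes. SMED_05706_V2_1 (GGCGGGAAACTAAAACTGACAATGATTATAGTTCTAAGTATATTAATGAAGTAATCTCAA) stood at 0.76 ± 0.01 in unirradiated and -0.42 ± 0.38 in irradiated fragments at 6 h, and at 0.04 ± 0.21 and -1.47 ± 0.09 at 12 h. The differences were -1.18 (limma's adjusted p = 0.016) and -1.51 (adjusted p = 6.6e-04). At 30 min, SMED_05152_V2_1 (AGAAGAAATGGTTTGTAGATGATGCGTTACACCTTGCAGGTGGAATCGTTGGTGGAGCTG) stood at 1.15 ± 0.39 in unirradiated and -0.47 ± 0.16 in irradiated fragments, and SMED_03729_V2_1 (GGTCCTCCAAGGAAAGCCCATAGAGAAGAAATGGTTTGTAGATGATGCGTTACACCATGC) at 0.82 ± 0.33 and -0.57 ± 0.19. Both differences had a limma adjusted p of 0.0496, and both probes share a run of 33 bases, so they may count as 1 signal. The differences were negative at every time, from -1.62 to -0.79 for SMED_05152_V2_1 and from -1.39 to -0.46 for SMED_03729_V2_1. In the authors' values they were also negative at every time, but smaller at 30 min (-1.08 and -1.03). There SMED_05152_V2_1 stood at -0.003 in unirradiated and -0.198 in irradiated fragments at 1 h, and at 0.027 and -0.163 at 6 h. SMED_03729_V2_1 stood there at 0.209 and 0.077 at 1 h. The size of these differences thus depended on the processing. The F test between times called neither probe in either course (limma's adjusted p of at least 0.408). A difference particular to 30 min is therefore not shown. SMED_03729_V2_1 already differed at 0 h, by -0.77. No probe was called at 1 h or 3 h with limma, where 606 and 461 of 31459 probes had an unadjusted p under 0.05. Over all times the moderated F test called 6 probes.

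Chosen after its values were seen, SMED_07003_V2_1 (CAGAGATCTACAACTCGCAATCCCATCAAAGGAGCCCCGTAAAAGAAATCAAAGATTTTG) was among these 6, with a limma adjusted p of 0.021 for the F test. It stood at 2.08 ± 0.13 at 3 h and 1.99 ± 0.86 at 6 h in unirradiated fragments. In irradiated fragments its control was not well above background on any of the 3 arrays at these times, so no ratio is given at 3 h and only a bound of at least 1.34-fold at 6 h. Over both courses its control was well above background on 4 of 15 unirradiated and 1 of 15 irradiated arrays, so the size of its ratios is uncertain. For the late riser SMED_19200_V2_1, the difference at 12 h was -1.56 (95% interval -2.36 to -0.75), with an adjusted p of 0.346. SMED_05893_V2_1, also chosen after its values were seen, had a lower limma adjusted p for that F test than SMED_07003_V2_1, 8.6e-04. At 6 h it stood at 1.08 in unirradiated and 0.18 in irradiated fragments. This difference of -0.91 (limma's adjusted p = 0.0011) was short of the fold threshold. At 0 h it was 2.73-fold lower after irradiation.

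**Figure D3:**
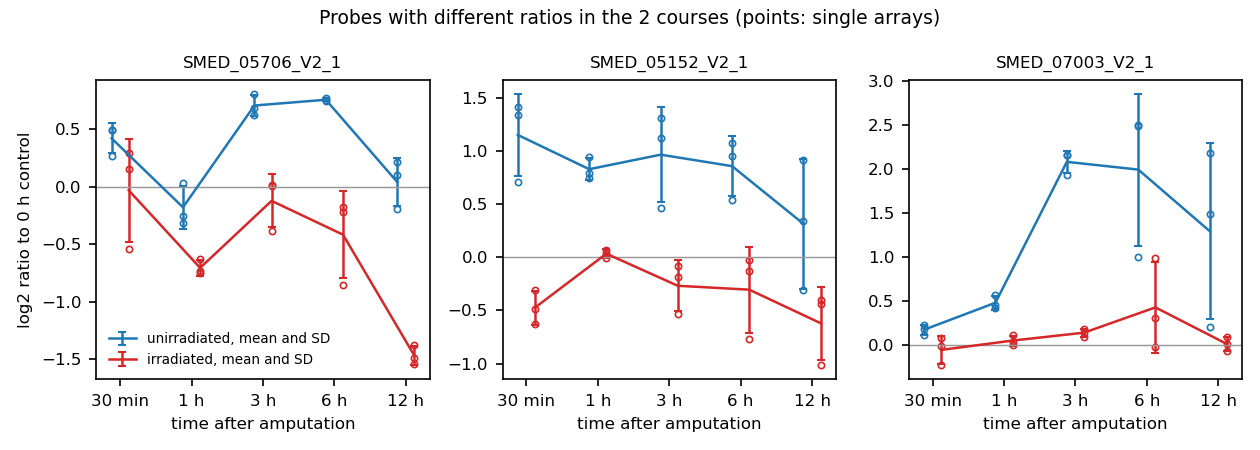
Log2 ratio of wounded fragments to the 0 h control of the same treatment (vertical axis) against time after amputation in equal steps (horizontal axis) for 3 of the 6 probes called by the F test between treatments; blue is unirradiated, red is irradiated, open circles are single arrays and bars are the SD of 3 arrays. SMED_05706_V2_1 stands at 0.04 in unirradiated and -1.47 in irradiated fragments at 12 h, while most control signals of SMED_07003_V2_1 were not well above background.

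The number of differences depended on the processing. With Feature Extraction's processed signals, 39 probes were called higher and 19 lower in irradiated fragments at 1 h, 26 and 24 at 3 h, 69 and 37 at 6 h, and 18 and 9 at 12 h, and the F test called 332. Without background subtraction the F test called 82, and with array weights, estimated gene by gene, 1604. With centring on the array median, 17 were called higher and 1 lower at 12 h, but SMED_05706_V2_1 was not called there (-1.12, limma's adjusted p = 0.232) or at 6 h (-1.54, adjusted p = 0.202). The 30 min calls were lost without any 1 of unirradiated replicates 2 and 3 and irradiated replicates 1, 2 and 3, while the log2 differences stayed between -1.49 and -1.71 for SMED_05152_V2_1 and between -1.25 and -1.48 for SMED_03729_V2_1. At 6 h the count was 0 without unirradiated replicate 1 or 3 or irradiated replicate 2, and 2 without unirradiated replicate 2 or irradiated replicate 1. SMED_05706_V2_1 was not among the calls without unirradiated replicate 2 (-1.18, limma's adjusted p = 0.065). With slide as a fixed effect, the difference rests on the 1 irradiated array of slide 4. That setting therefore cannot show whether a call holds. Its log2 differences were -1.95 at 6 h and -2.30 at 12 h for SMED_05706_V2_1. At 30 min they were -2.27 for SMED_05152_V2_1 and -1.93 for SMED_03729_V2_1. Without irradiated replicate 3 at 6 h, which leaves replicate 2 with 1 other array, the count was 1741. At 12 h it was 3 without unirradiated replicate 3 and 2 without irradiated replicate 1. The F test called 13 without irradiated replicate 2 at 6 h and 18 without replicate 3. With run as a random block it called 2, and without the first run 1. With run as a random block the calls at 30 min and 6 h were lost (limma's adjusted p = 0.181 for SMED_05152_V2_1 and SMED_03729_V2_1, 0.0777 for SMED_05706_V2_1) and the 12 h call of SMED_05706_V2_1 stayed (adjusted p = 0.0047). Without the first run all of these calls were lost, with log2 differences of -1.85 for SMED_05152_V2_1 and -1.57 for SMED_03729_V2_1 at 30 min, and of -1.17 at 6 h and -1.48 at 12 h (limma's adjusted p = 0.054) for SMED_05706_V2_1.

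Responses of both courses were positively correlated at every time. Across the 31459 probes, which are not independent replicates, Pearson r between unirradiated and irradiated mean ratios was 0.70 at 30 min, 0.77 at 1 h, 0.89 at 3 h, 0.43 at 6 h and 0.61 at 12 h. The SD of r between sets of replicates was 0.17, 0.11, 0.04, 0.28 and 0.17 at these times. After subtracting each course's 30 min ratio, which removes a constant dye effect, r was 0.68 at 1 h, 0.60 at 3 h, 0.32 at 6 h and 0.34 at 12 h. An effect of base composition that varies between arrays is not removed. The C count of a probe correlated with its log2 ratio at r from -0.563 to -0.016 over arrays. With the 12 h minus 30 min ratio, r was 0.29 in unirradiated and 0.23 in irradiated fragments for C. For T it was -0.30 and -0.14, while G and A had opposite signs in the courses. Of the 184 and 206 probes called higher at 3 h, 116 were shared. Shared higher calls numbered 50 at 30 min, 50 at 1 h, 49 at 6 h and 58 at 12 h, where independent lists would share 0.421 at 12 h, and no probe was called in opposite directions at the same time. The constant probes are part of these overlaps.

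Irradiated fragments differed from unirradiated fragments before any regeneration. At 0 h, 606 probes were called lower and 91 higher after irradiation. Without the minimum fold change the direction turned, with 6193 lower and 9593 higher, so the excess of lower probes holds for changes of at least 2-fold. The lowest was SMED_04036_V2_2 (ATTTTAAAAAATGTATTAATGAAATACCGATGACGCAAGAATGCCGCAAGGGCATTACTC), whose mean log2 Cy3 signal was 16.3 ± 0.135 (SD, n = 15) in unirradiated and 10.4 ± 0.671 (SD, n = 15) in irradiated fragments. Its log2 difference was -5.58 (SE 0.208, limma's adjusted p = 2.9e-21) with slide as a random block. The 15 channels of a treatment came from 3 runs, and Cy3 channels within a run had a median r of 0.997. The SDs, SEs and p-values of this paragraph therefore take arrays, not runs, as replicates, and do not measure the spread between runs. SMED_01436_V2_1 (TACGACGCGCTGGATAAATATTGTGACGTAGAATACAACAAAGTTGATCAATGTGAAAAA) was lower by nearly as much, -5.57 (SE 0.165). Among the probes that were higher, SMED_06445_V2_1 (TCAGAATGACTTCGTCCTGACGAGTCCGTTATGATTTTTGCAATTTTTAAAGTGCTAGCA) differed by 2.69 (SE 0.429). SMED_02253_V2_1r was also called, but no size is given, since its signal was well above background on 1 of 15 unirradiated arrays against 15 of 15 irradiated ones. Of the 606 lower probes, 138 were lower by at least 4-fold, 43 by at least 8-fold and 19 by at least 16-fold. The late riser SMED_19200_V2_1 was lower by 7.98-fold at 0 h after irradiation.

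Other comparisons used the same channels. With the mean control per run as the replicate, 3 against 3, 605 probes were called lower and 148 higher, and 584 of the 606 were again called lower. Feature Extraction's processed signals gave 1324 lower and 1180 higher calls. In a fit of both dyes, the 605 lower probes with a value on every array had a median log2 difference of -1.42 at 0 h and between -1.43 and -1.58 at the 5 later times, when 505 to 559 of them were called lower. Since each run held 1 treatment, run and treatment are told apart only by the 3 runs of each.

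**Figure D4:**
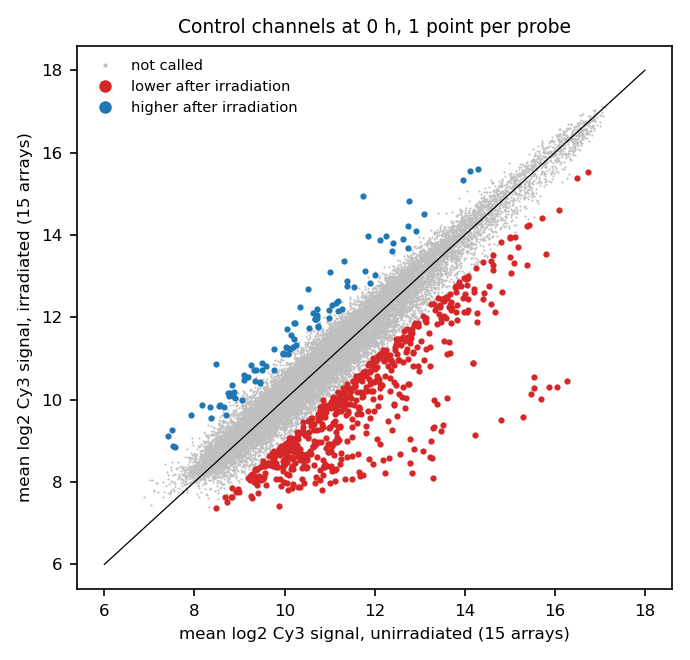
Mean log2 Cy3 signal of the 0 h control in irradiated (vertical axis) against unirradiated (horizontal axis) fragments, 1 point per tested probe and 15 arrays per treatment, with the line of equality. The 606 probes called lower after irradiation (red) lie below the line, with SMED_04036_V2_2 at 16.3 and 10.4, and the 91 called higher (blue) lie above it.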

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

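Of the tests in this part, those on base composition, on brightness, on the SD and the array of widest ratios and on the spread shared within runs were chosen only after the result was seen. Groups of 3 arrays were not screened for outlying arrays.

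A difference between the treatments was called for 3 probes by a test of the difference itself, though not under every setting. SMED_05706_V2_1 had an irradiated minus unirradiated log2 ratio of -1.18 at 6 h and -1.51 at 12 h. SMED_05152_V2_1 differed by -1.62 and SMED_03729_V2_1 by -1.39 at 30 min. Both of these share a run of 33 bases and may count as 1 signal. In the 10 splits of the 6 arrays of a time into 3 and 3, the real split called 2 probes at 30 min, 1 at 6 h and 1 at 12 h, and the highest other split called 0 at each of these times. As large a count as the real one came from 1 of 10 splits at each. At 1 h and 3 h the real split called 0, as did all 10. With 10 splits no share under 0.05 can be reached. With run as a random block the counts were 0 at 30 min, 0 at 6 h and 1 at 12 h, and without the first run 0 at each, although the log2 differences without that run were -1.85 and -1.57 at 30 min, -1.17 at 6 h and -1.48 at 12 h.

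Over all times, 6 probes were called by the F test between treatments, among them SMED_05152_V2_1 and SMED_03729_V2_1, which may count as 1 signal. Redrawing treatment labels within each time gave as many in 2 of 100 draws, the real one included, and 1 draw called 199. That draw left 36 pairs of arrays of a run on the same side, where the median was 30 and the draw with the most, 44, called 0, so its count does not follow from runs staying together. These draws break up the runs, so a share under 0.05 speaks only to the placing of single arrays. Chance is not excluded by them for the placing of runs. With runs kept whole, the real split called 6 and the highest of the 9 others 1, and 10 splits cannot give a share under 0.05. The count was 2 with run as a random block and 1 without the first run. The low count was weighed against its possible technical sources. Spread shared within a run stays open. The moderated F test of treatment by time interactions in limma called 0 probes without run and 0 with run as a fixed effect, while probes with an unadjusted p under 0.05 rose at each time, from 65 to 316 at 1 h, to 561 at 3 h, from 2043 to 3708 at 6 h and from 1149 to 2468 at 12 h. Differences that are constant over time are not covered. Differences too small for 3 arrays against 3 stay open. At 1 h, 75% of simulated 2-fold differences had an adjusted p under 0.05 without the minimum fold change, but a simulation excludes nothing here, and SMED_19200_V2_1 did not pass at 12 h with a difference of -1.56 (limma's adjusted p = 0.346). Background correction stays open, as the F test called 332 probes with Feature Extraction's processed signals and 82 without background subtraction, each including all 6. Array weights gave 1604, but they were estimated gene by gene because the REML estimate did not converge. Which of these counts is nearer to the biological difference between the treatments was not tested.

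Changes between time points were called for 124 probes in unirradiated and 224 in irradiated fragments. Redrawing time labels over the 15 arrays of a course gave as many in 12 of 100 and 5 of 100 draws, with the highest other draw at 4515 and 1529. Chance is not excluded by this count, but these draws break up the runs, whose arrays share deviations. The highest draw placed 11 pairs of arrays of a run in the same group in unirradiated fragments, the most of any draw, but 4 in irradiated fragments, the median of the draws. In 20 draws that kept runs intact, the same fit called at most 0 against the real 124 in unirradiated and at most 42 against the real 224 in irradiated fragments. No draw within runs reached the real count, which argues against a chance placing of the times within runs. At 0 h, 697 probes were called, and 1 of 100 draws reached this, the real one, with the highest other at 0. These draws break up the runs, whose Cy3 channels are nearly alike (median r of 0.997). The count therefore speaks only to the placing of single channels, and chance is not excluded for the placing of runs. With runs kept whole the highest of the 9 other splits called 44, and 10 splits cannot give a share under 0.05.

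In all 10 groups, 18 probes were called higher and 3 lower, with median log2 ratios of 1.95 and -1.70. For the 18, base composition is argued against as the whole source, since 15 stayed called in all 10 groups after its correction and their median ratio was 1.66. A dye difference at the top of the brightness range may account for 16 of them, which lie in the brightest 1% of the probes, but only 5.08% of the 315 probes in that range behaved so. For the 3 lower probes, which hold 26 to 28 C against a median of 11, base composition may be the source, since 0 stayed called in all groups after the correction and their median ratio moved to -0.99, just short of the fold threshold. No group of these samples separates a lasting wound response from a dye effect, so no biological explanation was tested.

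The 862 probes called in irradiated fragments at 6 h may largely come from 1 array with widely spread ratios. Without replicate 2 the count was 184, below the 288 called at 3 h in that course from 3 arrays. It was also below the 214, 262 and 399 called at 3 h without replicates 1, 2 and 3. A wider response at 6 h stays open, since the SD of the log2 ratios was 0.402 and 0.423 in the other replicates, between the median (0.351) and the highest (0.461) of the 12 irradiated arrays of other times.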

How the results depend on the processing

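Under other settings, counts of called probes stayed close to their value in 267 cases and moved in 178. Named probes kept their direction, and an adjusted p under 0.05 where there was a test, in 722 cases, no longer had such a p in 63, and moved by more than their SD without a test in 15. The size is not part of this count, and SMED_27563_V2_1 at 6 h in irradiated fragments went from 2.39 to 0.12 without background subtraction. The counts that moved are given here. Counts named for the largest change are probes whose largest absolute change fell at that time. The more frequent direction of the calls turned in several cases. Higher and lower calls were 724 and 971 with Feature Extraction's processed signals in unirradiated fragments at 12 h, and 2710 and 1827 in irradiated fragments at 6 h. In irradiated fragments they were 61 and 58 without background subtraction and 170 and 69 with centring at 30 min, and 4251 and 65 with centring and 342 and 107 with array weights at 6 h. In unirradiated fragments at 30 min they were 82 and 105 with array weights and 90 and 161 without the first run. Without replicate 1 they were 87 and 124 there, and without replicate 2 they were 133 and 51 in irradiated fragments at 6 h. Without a minimum fold change they were 216 and 241 at 1 h and 3621 and 3949 at 3 h in irradiated fragments, and 9593 and 6193 at 0 h. Against the 30 min ratio they were 6 and 7 in unirradiated fragments at 6 h. For the difference they were 69 and 37 at 6 h and 18 and 9 at 12 h with the processed signals, 17 and 1 with centring and 24 and 2 with array weights at 12 h. The direction also turned with slide as a fixed effect, but that difference rests on 1 irradiated array, so its counts are not given.

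With Feature Extraction's processed signals, the calls were for unirradiated fragments 1085 at 30 min, 2244 at 1 h, 2616 at 3 h, 1602 at 6 h and 1695 at 12 h, and for irradiated fragments 1480 at 30 min, 1979 at 1 h, 2163 at 3 h, 4537 at 6 h and 1805 at 12 h. Further calls were for the difference 1 at 30 min, 58 at 1 h, 50 at 3 h, 106 at 6 h and 27 at 12 h, and for the largest unirradiated change 302 at 30 min, 1065 at 1 h, 1453 at 3 h, 383 at 6 h and 897 at 12 h. It gave, in addition, for the largest irradiated change 705 at 30 min, 829 at 1 h, 669 at 3 h, 3254 at 6 h and 438 at 12 h, and for the unirradiated change over time 193. Beyond these, the calls were for the difference over all times 332, and for the 0 h comparison 2504. Without background subtraction, the calls were for unirradiated fragments 64 at 30 min, 73 at 1 h, 87 at 3 h and 208 at 12 h, and for irradiated fragments 119 at 30 min and 132 at 3 h. The same choice gave for the difference 1 at 3 h, 2 at 6 h and 7 at 12 h, and for the unirradiated change over time 239. Further calls were for the irradiated change over time 642, and for the difference over all times 82. With centring on the array median, the calls were for unirradiated fragments 440 at 30 min, 644 at 1 h, 790 at 3 h and 7129 at 6 h, and for irradiated fragments 30 at 1 h, 600 at 3 h, 4316 at 6 h and 3540 at 12 h. It gave, in addition, for the difference 0 at 30 min, 1 at 3 h and 18 at 12 h, and for the unirradiated change over time 5. Beyond these, the calls were for the irradiated change over time 97, and for the difference over all times 16. Without the filter on dim probes, the calls were for the difference 0 at 30 min. With the stricter filter, which tests fewer probes, the calls were for unirradiated fragments 78 at 1 h and 106 at 3 h, and for irradiated fragments 180 at 30 min and 158 at 3 h. The same choice gave for the difference 4 at 12 h.

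With slide as a random block, the calls were for the unirradiated change over time 259, and for the irradiated change over time 544. With run as a random block, the calls were for the difference 0 at 30 min and 0 at 6 h, and for the difference over all times 2. With array weights, the calls were for unirradiated fragments 187 at 30 min, 307 at 1 h and 603 at 3 h, and for irradiated fragments 142 at 1 h and 449 at 6 h. Further calls were for the difference 4 at 1 h, 19 at 3 h, 2 at 6 h and 26 at 12 h, and for the unirradiated change over time 8133. It gave, in addition, for the irradiated change over time 3341, and for the difference over all times 1604. With slide as a fixed effect, the counts for the difference also moved, but they rest on 1 irradiated array and are not given. With run as a fixed effect, the calls were for the unirradiated change over time 540, and for the irradiated change over time 957. With the arrays of 1 group alone, which leaves 2 residual degrees of freedom, the calls were for unirradiated fragments 6 at 30 min, 0 at 3 h, 7 at 6 h and 0 at 12 h, and for irradiated fragments 0 at 6 h. With the arrays of 1 time alone, the calls were for the difference 0 at 30 min, 1 at 3 h, 0 at 6 h and 0 at 12 h. With the arrays of the course alone, the calls were for the unirradiated change over time 52. Without a minimum fold change, which admits more probes by construction, the calls were for unirradiated fragments 4318 at 30 min, 6107 at 1 h, 6903 at 3 h, 2429 at 6 h and 869 at 12 h, and for irradiated fragments 6979 at 30 min, 457 at 1 h, 7570 at 3 h, 12509 at 6 h and 3418 at 12 h. Beyond these, the calls were for the difference 3 at 6 h, and for the largest unirradiated change 1995 at 30 min, 2950 at 1 h, 3568 at 3 h, 1157 at 6 h and 489 at 12 h. The same choice gave for the largest irradiated change 3973 at 30 min, 209 at 1 h, 4037 at 3 h, 8253 at 6 h and 1165 at 12 h, and for the 0 h comparison 15786. With a treat test against a 1.2-fold change, the calls were for unirradiated fragments 161 at 6 h, and for irradiated fragments 1411 at 6 h. Further calls were for the difference 0 at 30 min and 0 at 6 h. Against the 30 min ratio, the calls were for unirradiated fragments 0 at 1 h, 5 at 3 h, 13 at 6 h and 30 at 12 h, and for irradiated fragments 0 at 1 h, 8 at 3 h, 65 at 6 h and 99 at 12 h. With base composition corrected, the calls were for unirradiated fragments 52 at 30 min, 80 at 1 h and 103 at 3 h, and for irradiated fragments 134 at 30 min and 132 at 3 h. Without the first run, the calls were for unirradiated fragments 251 at 30 min, 350 at 1 h and 857 at 3 h, and for the difference 0 at 30 min, 0 at 6 h and 0 at 12 h. It gave, in addition, for the unirradiated change over time 59, and for the difference over all times 1.

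With each array left out in turn, the calls ranged in unirradiated fragments from 69 to 211 at 30 min, 72 to 336 at 1 h, 102 to 804 at 3 h, 62 to 151 at 6 h and 63 to 133 at 12 h. In irradiated fragments they ranged from 135 to 353 at 30 min, 48 to 154 at 1 h, 214 to 399 at 3 h, 184 to 2036 at 6 h and 177 to 399 at 12 h. The difference ranged from 0 to 2 at 30 min, 0 to 0 at 1 h, 0 to 0 at 3 h, 0 to 1741 at 6 h and 1 to 3 at 12 h. The F tests ranged from 85 to 256 for unirradiated change, 136 to 2673 for irradiated change and 4 to 18 for the difference. Left-out arrays reduce a group to 2, whose spread is taken as that of the other groups.

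The number of differences called at 30 min fell under several other settings, to 0 with centring on the array median and to 0 without the filter on dim probes, while the log2 differences of SMED_05152_V2_1 and SMED_03729_V2_1 were -1.99 and -1.79 with centring and -1.62 and -1.39 without the filter. All 6 probes of the F test of the difference were among the 332 called with Feature Extraction's processed signals and the 82 called without background subtraction. Tests of the gene lists, and their alternatives, were not run, because the probes are not paired with genes.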

Other observations

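Every test in this part was chosen after the result was seen, and the prediction for the probes lower at 0 h was written after similar medians of these probes had been looked at. The probes called lower at 0 h after irradiation were counted among the wound responses. In unirradiated fragments the set of 606 held 1 of the 114 probes called at 30 min (2.20 expected from its size), 0 of 151 at 1 h (2.91 expected) and 2 of 231 at 3 h (4.45 expected). At 12 h it held 6 of the 81 called probes (1.56 expected), all 6 of them higher, and at 6 h 5 of 96 (1.85 expected), all 5 higher. In irradiated fragments it held 0 of 274 at 30 min (5.28 expected), 0 of 79 at 1 h (1.52 expected) and 3 of 288 at 3 h (5.55 expected). At 12 h it held 14 of 242 called probes (4.66 expected), 3 higher and 11 lower, and at 6 h 41 of 862 (16.6 expected), 35 higher and 6 lower. Whether these shares differ between times was not tested, and the control channels enter both values.

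A candidate explanation is that transcripts lost with irradiation rise after wounding in unirradiated fragments and not in irradiated ones. To keep the selection apart from the measurement, the set was chosen for each run on the other 5 runs (592 to 613 probes), and the median log2 ratio of its members was taken per array. At 12 h it averaged 0.173 ± 0.084 (SD, n = 3 runs) in unirradiated and -0.011 ± 0.017 (SD, n = 3 runs) in irradiated fragments, with an exact two-sided permutation p of 0.1 and an adjusted p of 0.167 over 5 times. The exact permutation p was 0.3 at 30 min, 0.1 at 1 h (0.028 against -0.012) and 0.1 at 3 h (0.146 against 0.015). At 6 h the averages were 0.229 ± 0.053 (SD, n = 3 runs) and 0.214 ± 0.244 (SD, n = 3 runs), with an exact permutation p of 0.9. The irradiated value rested on run 5, which holds the array with the widest ratios, at 0.468 against -0.019 and 0.193, and was 0.087 without it. Averaged over the 5 times, the unirradiated runs lay 0.083 above the irradiated runs (exact permutation p = 0.2). Since 3 runs against 3 cannot go below 0.1, the hypothesis stays undecided.

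Probes against both strands of the same 60 bases gave related values. Of the identifiers ending in r, 2300 had an exact reverse complement among the tested probes. The partner without r was brighter by a median of 2.62 on the log2 scale. Their wound ratios correlated across pairs with r between 0.413 and 0.596 over the 10 groups, and their 0 h differences with r of 0.762. Of 58 partners called at 0 h, 24 of the r probes were called in the same direction, 55 had the same sign and 0 were called in the opposite direction.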
